A study of Mus musculus with 6 samples.

How the data were processed

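RNA was taken from the kidney cortex of mice that express I-PpoI in proximal tubular epithelial cells (PT-I-PpoI) and of wild type mice, with 3 libraries per group. I-PpoI is a homing endonuclease, an enzyme that cuts DNA at a long recognition site and leaves double-strand breaks. Per the labels' protocols, libraries were made with a stranded TruSeq kit for mRNA and read as pairs for 100 cycles on a NovaSeq 6000. The labels number the samples of each group but do not say that each came from its own mouse, so p-values measure the spread between these samples only.

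The authors deposited a table of raw read pair counts for 24421 genes. Reads were mapped with HISAT2, per the labels' protocols, and counted over the exons of each gene with featureCounts 1.5.2, per the file headers. The counting command in the header required both mates to be mapped and set no strand option, so reads of a gene and of an overlapping antisense gene cannot be told apart even though the kit keeps strand. It also set no option to count reads that map to several places or overlap several genes, so near-identical genes such as Hspa1a and Hspa1b, and members of the Gstm, Oas, Ifit, Cyp4a and Slc22a families, may be undercounted or share reads. The header names a UCSC mm10 gene annotation, whereas the labels' protocols name mm9. The coordinates in the count table were checked against reference gene positions by symbol: 99.34% of 23204 matched genes overlapped their position in GRCm38.p6 (mm10), and 11.75% of 20836 overlapped their position in NCBIM37 (mm9). Coordinates are therefore given as mm10, as in the table.

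The authors also deposited a table of log2 values on the regularized log2 (rlog) scale, which corrects for library size, and DESeq2 is named in the submitters' processing notes. It held 17918 genes, those with a summed count of at least 2, and differed by at most 0.000793 on the log2 scale from rlog values recomputed from the counts. It was used only for an alternative test.

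Gene tests used the counts as deposited, in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter with its defaults (a minimum count of 10), which left 13977 genes. Library sizes were scaled by TMM factors, and groups were compared with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are PT-I-PpoI relative to wild type, with standard errors (SE) on the log2 scale. Levels are in CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD. On simulated counts for the 13977 genes of this comparison, with 200 genes changed in each of 5 runs, the procedure recovered 37.5% of the 1.5-fold changes, 79.6% of the 2-fold changes and 91.2% of the 3-fold changes. Over the 5 runs, 8.29% of its calls were false. Each gene was drawn independently, with a spread estimated from the real counts with the group alone. Differences between the library name forms described below thus entered only as noise, and the runs gave a mean of 152 calls. These shares need not hold for the real counts.

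Before the data were examined, 32 gene lists were fixed. They cover p53 targets, double-strand break repair, the cell cycle, tubular injury, nephron segments, other kidney and immune cell types, interferon-stimulated genes, secreted factors, metabolism, stress, neighbouring tissues, the circadian clock and sex chromosomes. Lists were compared with the remaining genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 32 lists. The same test with a correlation estimated for each list, and fry, which asks whether a list's genes moved on balance in 1 direction, were run beside it. A list score is the mean over its members of log2 CPM centred on each gene's mean over the 6 libraries. The named genes were also fixed by rule. The rule takes up to 8 genes per direction with the largest change among those that passed, had a mean of at least 1 CPM in the higher group and did not overlap between groups, leaving out predicted genes. For each list it takes up to 3 members with the smallest p, and the smallest p in the other direction where these differ from the list's direction. It also takes any gene that passed from the fixed list of Y-linked genes and Xist or from that of DNA methylation enzymes, and none did. Any other gene is said to have been chosen after its values were seen. One gene that passed is not reported here by name.

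Other size factors, filters and thresholds, the replicate number as a block, DESeq2 1.42.0, limma-voom, limma on the deposited rlog values, and leaving out each library in turn were tried as alternatives. The deposited library names take 2 forms, with a hyphen before the final number (PT-I-PpoI replicate 3, wild type replicates 2 and 3) or without (PT-I-PpoI replicates 1 and 2, wild type replicate 1). The labels do not call this a batch. After the main axis of variation had been seen to follow it, the tests were repeated with the name form as a term and fold changes were computed within each form, where too few libraries remain for a test. All pairs of libraries differed by more than sampling noise, so none was the same library sequenced again. Such a check cannot tell whether different libraries came from the same mouse.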

Results

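Gene expression was measured by RNA-seq in kidney cortex from mice with expression of the endonuclease I-PpoI in the proximal tubular epithelium (PT-I-PpoI, 3 libraries) and from wild type mice (3 libraries). The comparison asks how the cortical transcriptome differs when proximal tubule cells carry an enzyme that makes DNA double-strand breaks. Total counts ranged from 13.6 to 20.9 M read pairs per library. The transgene itself was not analysed here. Along the first principal component (43.1% of the variance) the libraries separated by the form of their library name, while the groups overlapped. Within each form PT-I-PpoI lay lower, at -23.1 and -30.15 against -0.54 without a hyphen and 11.84 against 20.43 and 21.52 with one. Medians of each list within libraries whose names lack a hyphen (2 PT-I-PpoI, 1 wild type) and within those with one (1 PT-I-PpoI, 2 wild type) are therefore given beside the pooled medians, in that order. Medians without a hyphen rest on wild type replicate 1 alone for their group, a library that lay apart on the second component (29.22, against 0.13 or less).

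PT-I-PpoI cortex had higher levels of genes of the thick ascending limb and the collecting duct, nephron segments beyond the proximal tubule (camera adjusted p = 5.47e-11 and 4.09e-09 for the lists, and adjusted p = 0.176 and 0.0775 with an estimated correlation). More medulla in the dissected tissue may account for this, a question that the data could not decide. In all, 19 of 13977 genes rose and 0 fell. The largest rise was that of Tnn, which encodes the matrix glycoprotein tenascin-N, at 5.37-fold. Leaving out predicted genes, next came Slc4a11, a membrane transporter, at 3.28-fold, and Aldoc, the glycolytic enzyme aldolase C, at 2.37-fold. None of the p53 targets, double-strand break repair genes or cell cycle genes passed the test.

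Tnn (chromosome 1, 160085032 to 160153575, mm10) was at 6.77 ± 0.96 CPM in PT-I-PpoI and 1.29 ± 0.34 CPM in wild type (SD, n = 3 each), a log2 fold change of 2.42 ± 0.23 (SE; adjusted p = 0.0229, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all gene values here). Slc4a11 (chromosome 2, 130684108 to 130697519) was at 17.5 ± 1.73 against 5.38 ± 0.94 CPM, a log2 fold change of 1.71 ± 0.15 (edgeR adjusted p = 0.0229). Aldoc (chromosome 11, 78323073 to 78327778) was at 31.5 ± 2.54 against 13.4 ± 2.41 CPM, with a log2 fold change of 1.25 ± 0.14 (edgeR adjusted p = 0.0356). Cryab (chromosome 9, 50751325 to 50756635), the small heat shock protein alpha B-crystallin, rose from 62.7 ± 14.2 to 145 ± 12.2 CPM (log2 fold change 1.21 ± 0.15). Its exons overlap those of Hspb2, and the counting did not use strand. Slco4a1 (chromosome 2, 180460978 to 180474853), an organic anion transporter, had a log2 fold change of 1.17 ± 0.15. Apela (chromosome 8, 65028417 to 65037336), a peptide ligand of the apelin receptor, rose by 1.04 ± 0.13 on the log2 scale, from 27.1 to 55.7 CPM.

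Of the 19 genes, 4 belonged to the thick ascending limb or collecting duct lists. The remaining 9 rose by 1.53-fold to 2.46-fold and included Gstm2, Gpx6, Pla1a, Scin, Cd82, Tspan8, Litaf and the predicted gene A130010J15Rik. Those listed were chosen after their values were seen. The exons of A130010J15Rik overlap those of Traf3ip3. The calls of A130010J15Rik, Cd82, Tspan8 and Litaf (edgeR adjusted p = 0.0496 each) ended with DESeq2's size factors, with a CPM of at least 1 in 3 libraries, with limma-voom and with limma on the rlog values, and, Cd82 apart, with upper-quartile factors. All 19 genes were higher in every PT-I-PpoI library than in every wild type library. Among all tested genes 17% did not overlap between the groups in either direction, where chance gives 10%. Within libraries without and with a hyphen, the log2 differences were 2.72 and 1.92 for Tnn, 1.67 and 1.74 for Slc4a11 and 1.51 and 1.02 for Aldoc.

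**Figure D1:**
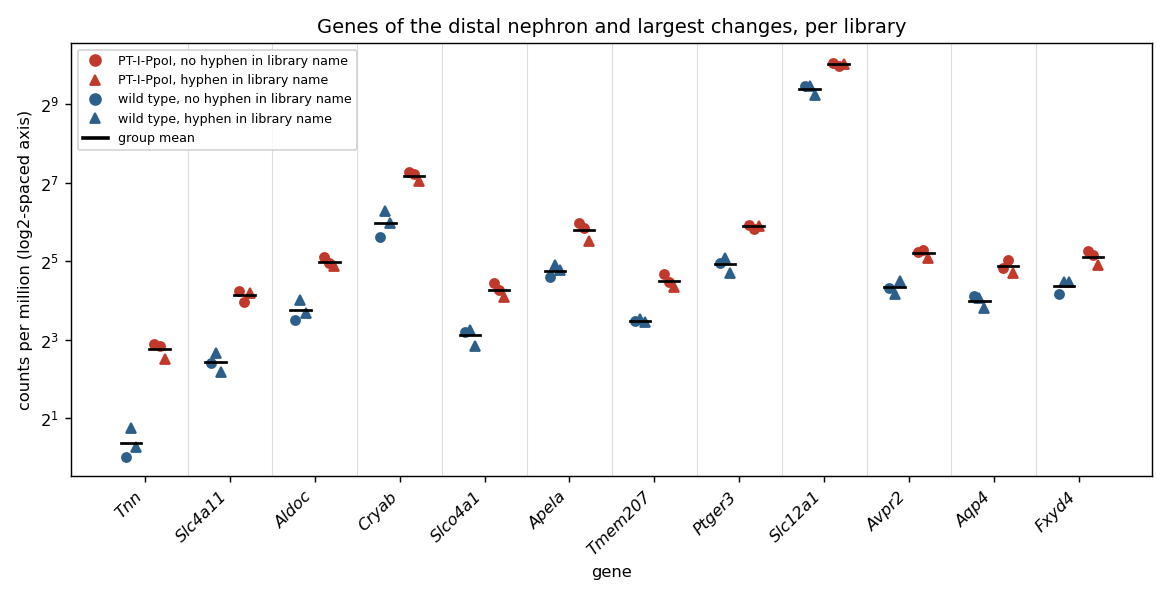
CPM (log2-spaced vertical axis) of the 8 genes with the largest change, predicted genes left out, and of further thick ascending limb and collecting duct genes, 1 point per library, with bars at the group means (n = 3 each). Triangles are libraries with a hyphen in their name and circles those without. Tnn lies at 5.67 to 7.46 CPM in PT-I-PpoI and 1.01 to 1.67 CPM in wild type.

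All 12 thick ascending limb genes had fold changes above 0, with a median log2 fold change of 0.44. Of these, 2 rose after adjustment over all genes, 4 with the name form as a term, 6 by DESeq2 and 9 when adjusted over the list alone. Ptger3 (chromosome 3, 157566892 to 157644758), a prostaglandin E2 receptor, rose by 0.97 ± 0.10 on the log2 scale, from 30.2 ± 4.0 to 59.1 ± 2.05 CPM (edgeR adjusted p = 0.0356). Tmem207 (chromosome 16, 26503793 to 26526771), a transmembrane protein, rose by 1.03 ± 0.12, from 11.1 to 22.7 CPM. Slc12a1, the sodium-potassium-chloride cotransporter that marks the segment, was at 1037 ± 27.0 against 671 ± 56.3 CPM (log2 fold change 0.63 ± 0.10, edgeR adjusted p = 0.0641, or 0.0294 with the name form as a term). The list was higher than other genes by camera (adjusted p = 5.47e-11), but not when its correlation was estimated (adjusted p = 0.176 with an estimated correlation). fry gave an adjusted p of 0.00622. The median was 0.42 within libraries without a hyphen and 0.41 within those with one. Scores ran from 0.16 to 0.30 in PT-I-PpoI and from -0.31 to -0.23 in wild type.

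All 17 collecting duct genes likewise lay above 0, with a median log2 fold change of 0.36. Adjusted over all genes 2 rose, as with the name form as a term, 6 by DESeq2, and 11 when adjusted over the list alone. Avpr2 (chromosome X, 73892102 to 73894428), the vasopressin receptor of principal cells, rose by 0.86 ± 0.11 on the log2 scale, from 20.1 to 36.7 CPM. It shares exon sequence with Arhgap4. Aqp4 (chromosome 18, 15389394 to 15410982), a basolateral water channel, rose by 0.87 ± 0.12 (edgeR adjusted p = 0.0496), a call that ended with DESeq2's size factors, with upper-quartile factors, with a CPM of at least 1 in 3 libraries and with limma-voom. Fxyd4, a regulator of the sodium pump, had a log2 fold change of 0.75 ± 0.13 (edgeR adjusted p = 0.0757). The camera adjusted p of the list was 4.09e-09, and the adjusted p = 0.0775 with an estimated correlation. fry gave 0.00166. Within-form medians were 0.43 without and 0.33 with a hyphen. A score of 5 medullary genes minus a score of 12 genes of cortex-only segments and cells, both written after the first results had been seen, was 1.27 higher in PT-I-PpoI on the log2 scale (SD 0.43), and 1.61 and 1.20 higher within the forms. Among the cortex-only genes, Slc26a4 and Slc4a9 of the collecting duct list had log2 fold changes of 0.13 ± 0.15 and 0.14 ± 0.12. Hmx2, outside that list, was at 0.77 ± 0.17 (edgeR adjusted p = 0.189). These were chosen after their values were seen. Distal convoluted tubule genes, from the segment between the thick ascending limb and the collecting duct, had a median of -0.18 over 11 genes and were not called (camera adjusted p = 0.0521), at -0.45 and 0.11 within the name forms. None of them passed.

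**Figure D2:**
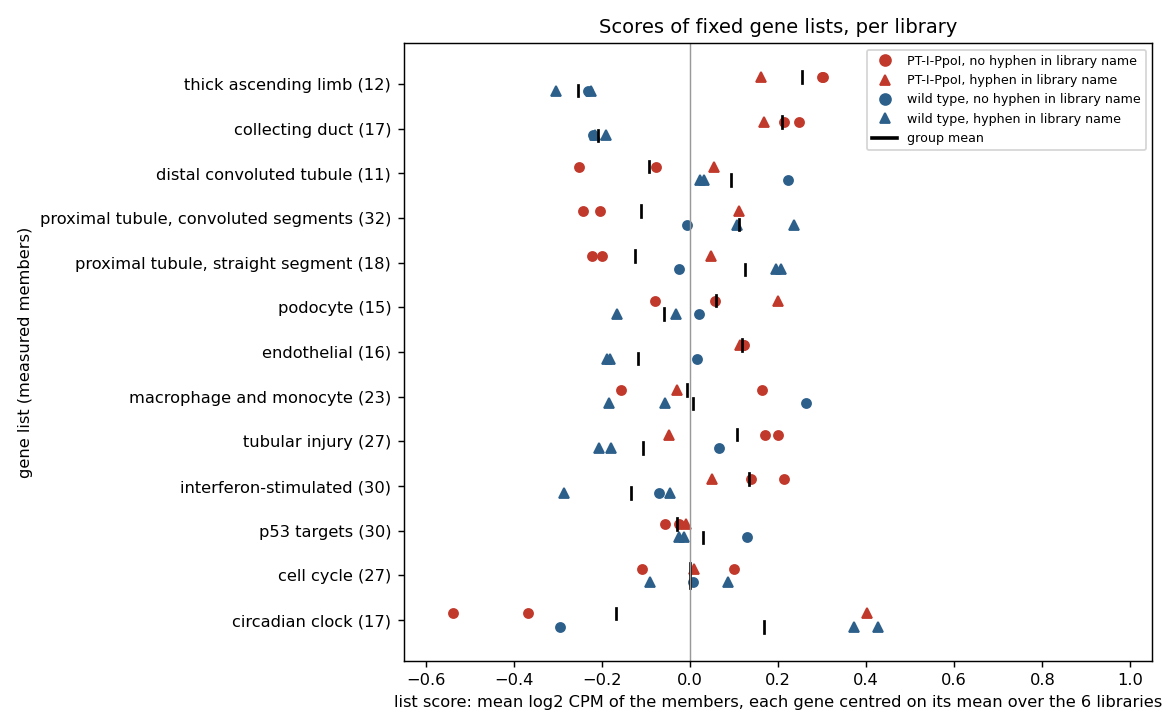
Scores of 13 fixed gene lists (mean centred log2 CPM of the members, horizontal axis), 1 point per library, with bars at the group means (n = 3 each) and the number of measured genes in brackets. Thick ascending limb and collecting duct scores do not overlap between the groups, at 0.16 or more in PT-I-PpoI and -0.19 or less in wild type. Circadian clock scores separate by the form of the library name instead.

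Proximal tubule genes mostly had fold changes below 0. Of 32 genes of the convoluted segments, 28 had fold changes below 0 and the median log2 fold change was -0.22, although 0 passed by edgeR, 0 by DESeq2 and 0 when adjusted over the list alone (6 lower and 0 higher at an unadjusted p under 0.05). Slc13a1, a sulfate transporter, was at 384 ± 21.6 against 467 ± 8.49 CPM, and Slc22a6, the organic anion transporter OAT1, at 971 ± 161 against 1383 ± 297 CPM. The list was lower by camera (adjusted p = 1.06e-05), but the adjusted p = 0.595 with an estimated correlation. Its within-form medians were -0.17 and -0.10. Genes of the straight segment had a median of -0.33 over 18 genes, with 0 passing over all genes by edgeR (1 higher and 9 lower at an unadjusted p under 0.05), 6 lower by DESeq2, and 7 lower by edgeR when adjusted over the list alone. With the name form as a term, edgeR called 2 of them lower, Atp11a (edgeR adjusted p = 0.0390) and Cyp4b1 (edgeR adjusted p = 0.0452), both chosen after their values were seen. Slc22a30 had a log2 fold change of -0.59 ± 0.13 (edgeR adjusted p = 0.189) and Slc5a8, a monocarboxylate transporter, one of -0.55 ± 0.14. The camera adjusted p of this list was 0.00979, and the adjusted p = 0.585 with an estimated correlation. Its medians were -0.32 without and -0.22 with a hyphen. Androgen-responsive proximal tubule genes had a median of -0.46 over 9 genes (camera adjusted p = 0.0109; adjusted p = 0.585 with an estimated correlation), but -0.44 and 0.03 within the forms, and the camera call was lost without PT-I-PpoI replicate 1. Odc1, the rate-limiting enzyme of polyamine synthesis, was at 338 ± 65.1 against 669 ± 217 CPM. It was among 3 genes of that list that were lower when adjusted over the list alone. Over all genes 0 of the list passed by edgeR (0 higher and 3 lower at an unadjusted p under 0.05), 2 were lower by edgeR with the name form as a term and 3 were lower by DESeq2. Both proximal tubule lists and the androgen-responsive list were higher in hyphenated libraries (medians 0.21, 0.28 and 0.45; adjusted p = 0.357, 0.323 and 0.323 with an estimated correlation), the form with more wild type libraries.

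With the name form as a term, edgeR's quasi-likelihood test called 49 genes higher and 15 lower, and all 19 genes were kept. The following were chosen after their values were seen. Slc14a2, a urea transporter of the inner medulla, was at 90.4 ± 11.1 against 18.5 ± 11.5 CPM and rose in this fit (log2 fold change 2.70 ± 0.40, edgeR adjusted p = 0.0390; 2.32 ± 0.42 and 0.105 without the term). Slc5a3, the myo-inositol transporter, rose by 0.78 ± 0.07 (edgeR adjusted p = 0.0106, or 0.57 ± 0.21 and 0.3615 without the term). Its position overlaps that of Mrps6, a gene on the same strand that also rose in this fit. Of the 15 lower genes, Cyp24a1, the vitamin D 24-hydroxylase, had a log2 fold change of -1.74 ± 0.27 (edgeR adjusted p = 0.0436; -1.26 ± 0.58 and 0.427 without the term). Odc1 was at -0.71 ± 0.11, Fmo5 at -0.62 ± 0.09 and Cyp4b1 at -0.48 ± 0.08. Of the 15, 11 did not overlap between the groups. Cyp24a1 was not among these, at 40.11 to 164.5 CPM in PT-I-PpoI and 103.4 to 416 CPM in wild type.

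The lists closest to the DNA damage question were not called. p53 targets had a median log2 fold change of -0.08 over 30 genes (camera adjusted p = 0.258), with 0 passing by edgeR or DESeq2 and 2 higher and 3 lower at an unadjusted p under 0.05. Within the name forms the median was -0.13 and 0.04. Ephx1, an epoxide hydrolase, had the smallest p, at 74.0 ± 9.27 against 58.1 ± 2.90 CPM, followed by Perp at 74.3 ± 4.79 against 89.1 ± 3.77 CPM. Cdkn1a (p21) and Mdm2, chosen after their values were seen as the best-known targets, had log2 fold changes of -0.08 ± 0.30 and 0.00 ± 0.07. Double-strand break repair and checkpoint genes had a median of -0.02 over 28 genes (camera adjusted p = 0.489), and 0 passed by edgeR or DESeq2, with 0 higher and 1 lower at an unadjusted p under 0.05. The within-form medians were -0.07 and -0.02. The gene with that p was Xrcc5 (Ku80), at 58.2 ± 3.31 against 65.5 ± 1.47 CPM. Over 27 cell cycle genes the median was 0.01, while the camera test leaned downwards (adjusted p = 0.927), and 0 passed by either tool or at an unadjusted p under 0.05. Its within-form medians, -0.05 and 0.07, differed in sign. DNA methylation enzymes had a median of -0.09 over 8 genes (camera adjusted p = 0.685) and ribosome biogenesis genes 0.02 over 28 (0.685), and none of them passed by edgeR or DESeq2. Their within-form medians were 0.03 and 0.14, and 0.03 and -0.02.

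Interferon-stimulated genes had a median log2 fold change of 0.28, with 26 of 30 genes above 0 (camera adjusted p = 3.41e-05), yet the adjusted p = 0.479 with an estimated correlation. None passed by edgeR or DESeq2, against 7 higher and 0 lower at an unadjusted p under 0.05. Oas2, an RNA sensor, was at 2.04 ± 0.38 against 1.03 ± 0.15 CPM, and Ifit3 at 15.6 ± 2.13 against 9.54 ± 2.67 CPM. Ifit3 rose with the name form as a term (log2 fold change 0.90, edgeR adjusted p = 0.0452). Within the name forms the list's median was 0.21 and 0.18. Tubular injury genes had a median of 0.27 over 27 genes (camera adjusted p = 0.00866; adjusted p = 0.583 with an estimated correlation), and 0.24 and 0.19 within the forms. The camera call was also lost without wild type replicate 2 (adjusted p = 0.0773). Over all genes 0 injury genes passed by edgeR (8 higher and 0 lower at an unadjusted p under 0.05) and 2 were higher by DESeq2, while 2 passed by edgeR when adjusted over the list alone. The latter were the keratins Krt18 (22.9 ± 2.14 against 15.9 ± 1.34 CPM) and Krt7 (135 ± 2.06 against 107 ± 6.42 CPM), which collecting duct cells also express. Of the 27 genes 17 had fold changes above 0 and 10 below. Injury markers chosen after their values were seen were Lcn2 (log2 fold change 0.85 ± 0.28, edgeR adjusted p = 0.322), Spp1 (0.06 ± 0.12), Havcr1 (-0.08 ± 0.45), Krt8 (-0.14 ± 0.10) and Vcam1 (-0.23 ± 0.30). Immediate early and heat shock genes had a median of 0.22 over 18 genes (camera adjusted p = 6.76e-04; adjusted p = 0.283 with an estimated correlation), and 0.30 and 0.24 within the forms. The smallest p was that of Hspa1b, at 20.5 ± 1.11 against 13.8 ± 2.53 CPM. None passed over all genes by edgeR (5 higher and 0 lower at an unadjusted p under 0.05), and 1 was higher by DESeq2. Antigen presentation genes had a median of 0.14 over 19 genes (camera adjusted p = 0.0142; adjusted p = 0.687 with an estimated correlation), but -0.02 and 0.19 within the forms, and its call was lost with the name form as a term (camera adjusted p = 0.06) and without PT-I-PpoI replicate 1, PT-I-PpoI replicate 3 or wild type replicate 3. Between the forms themselves, the tubular injury list was lower in hyphenated libraries (median -0.22; adjusted p = 0.323 with an estimated correlation).

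Secreted factors and senescence genes were not called as a list (camera adjusted p = 0.685 over 17 genes), and here the median (-0.05) and the mean (0.12) differed in sign. The within-form medians were 0.00 and -0.01. The largest fold change in the list was that of Cdkn2b, the cell cycle inhibitor p15, at 4.30 ± 1.17 against 1.18 ± 0.23 CPM. Its log2 fold change of 1.89 ± 0.27 missed the threshold over all genes (edgeR adjusted p = 0.0561), passed when adjusted over the list alone, passed with the name form as a term (1.80 ± 0.29, edgeR adjusted p = 0.0452), and was the 1 gene of the list that DESeq2 called. NRF2 targets had a median of -0.004 over 20 genes with the test leaning upwards (camera adjusted p = 0.941), and 0.16 and -0.15 within the forms. Macrophage and monocyte genes had a median of -0.03 over 23 genes, again with the test leaning upwards (camera adjusted p = 0.927), and the within-form medians, -0.25 and 0.19, differed in sign. T and NK cell genes (median -0.11, 12 genes), B and plasma cell genes (-0.43, 8 genes) and neutrophil genes (-0.02, 4 genes, test leaning upwards) had camera adjusted p of 0.927, 0.489 and 0.927. Their within-form medians were -0.47 and -0.10, -0.45 and -0.27, and -0.36 and 0.05. None of these immune cell genes passed by edgeR or DESeq2.

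Among other cell types, all 16 endothelial genes had fold changes above 0, with a median of 0.23 (camera adjusted p = 2.79e-05; adjusted p = 0.479 with an estimated correlation). Over all genes 0 passed by edgeR (7 higher and 0 lower at an unadjusted p under 0.05) and 1 was higher by DESeq2. By edgeR 1 passed with the name form as a term and 2 when adjusted over the list alone. Esam, an endothelial adhesion molecule, was at 41.5 ± 2.43 against 29.3 ± 0.99 CPM, and the list's within-form medians were 0.08 and 0.28. Extracellular matrix and fibroblast genes had a median of 0.14 over 24 genes (camera adjusted p = 0.0142; adjusted p = 0.687 with an estimated correlation), with Acta2 at 35.8 ± 2.48 against 26.9 ± 2.21 CPM, and 0.07 and 0.03 within the forms. That call, too, was lost with the name form as a term (camera adjusted p = 0.06), and without PT-I-PpoI replicate 1 or wild type replicate 3. Podocyte genes (median 0.19, 15 genes) and smooth muscle and pericyte genes (0.16, 9 genes) were not called, with camera adjusted p of 0.0835 and 0.258. Within the forms they had medians of 0.02 and 0.29, and 0.15 and -0.02. Neither were the 4 measured genes of adrenal, fat, muscle and blood called (median -0.43, camera adjusted p = 0.685), at -1.31 and 0.78 within the forms. The renin-angiotensin list was not called either (median -0.17, 7 genes, camera adjusted p = 0.619; -0.22 and -0.10 within the forms), although angiotensinogen (Agt, 95.0 ± 6.43 against 74.5 ± 5.27 CPM) passed when adjusted over the list alone.

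Of the metabolic lists, only glycolysis was called, with a median of 0.13 over 16 genes (camera adjusted p = 0.0385; adjusted p = 0.479 with an estimated correlation) and 0.09 and 0.10 within the forms. The camera call was lost without PT-I-PpoI replicate 3 or wild type replicate 1, with other filters and with the replicate number as a block. Hexokinase Hk1 (168 ± 13.5 against 119 ± 3.57 CPM), Pfkp and the glucose transporter Slc2a1 were the 3 genes that passed when adjusted over the list alone. Over all genes 0 passed by edgeR (5 higher and 0 lower at an unadjusted p under 0.05), 1 was higher by edgeR with the name form as a term and 3 were higher by DESeq2. Fatty acid oxidation and PPAR-alpha targets had a median of 0.19 over 30 genes (camera adjusted p = 0.0571) and oxidative phosphorylation genes 0.04 over 35 (0.0997), with 0.14 and 0.02, and 0.02 and 0.07 within the forms. Circadian clock genes had a median of -0.40 over 17 genes (camera adjusted p = 0.0835) and -0.23 and -0.05 within the forms. Between the forms the medians were 0.73 higher in hyphenated libraries for clock genes and -0.28 for fatty acid oxidation genes (adjusted p = 0.323 and 0.583 with an estimated correlation). The 4 measured sex chromosome genes, all Y-linked, had a median of -0.18 (camera adjusted p = 0.0427; adjusted p = 0.583 with an estimated correlation) and -0.24 and -0.07 within the forms. This call was lost with the name form as a term (camera adjusted p = 0.0882), with no filter, with the replicate number as a block and without any library but PT-I-PpoI replicate 3. Of the 32 lists 13 were called with the preset correlation, 10 of them also with the name form as a term, and 0 with an estimated correlation, with or without that term.

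**Figure D3:**
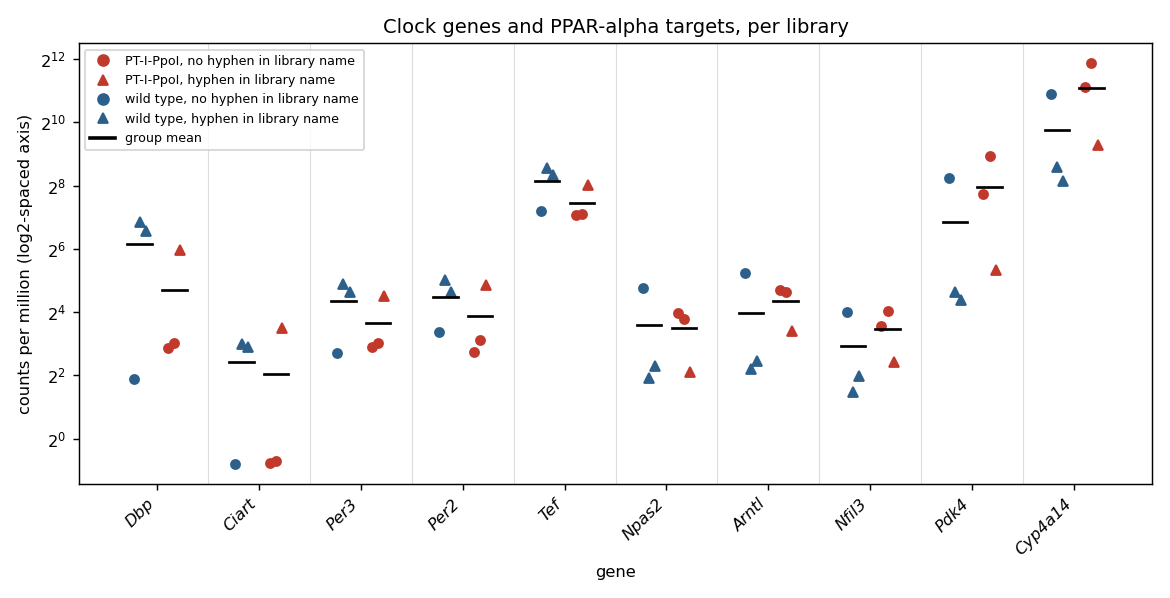
CPM (log2-spaced vertical axis) of clock genes and of the PPAR-alpha targets Pdk4 and Cyp4a14, chosen after their values were seen, 1 point per library, with bars at the group means (n = 3 each). Triangles (hyphen in the library name) and circles (no hyphen) separate in both groups, as for Dbp at 3.76 ± 0.33 higher (log2, SE) in hyphenated libraries.

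The number of called genes depended on single libraries. It fell from 19 to 0 without PT-I-PpoI replicate 1, PT-I-PpoI replicate 2 or wild type replicate 3, was 2 without wild type replicate 1 (0 of the 19 among them) and 9 without wild type replicate 2 (6 of the 19 among them), and came to 261 higher and 364 lower without PT-I-PpoI replicate 3, the only hyphenated library of its group. Of the lists not called, distal convoluted tubule genes were called lower by camera with the preset correlation, the only form of the test run on fewer libraries, without PT-I-PpoI replicate 1, PT-I-PpoI replicate 3, wild type replicate 2 or wild type replicate 3. Fatty acid oxidation genes were called higher without PT-I-PpoI replicate 1, PT-I-PpoI replicate 3 or wild type replicate 1 and with the replicate number as a block, and clock genes lower without PT-I-PpoI replicate 3 or wild type replicate 1 and with that block. Oxidative phosphorylation and podocyte genes were called higher without PT-I-PpoI replicate 1. DESeq2 called 126 genes higher and 61 lower, and at an unadjusted p under 0.05 edgeR's test gave 897 higher and 784 lower.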

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

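Tests with the name form as a term were chosen after seeing the data. All 19 genes kept a positive fold change under every alternative. Since none of them overlapped between the groups, leaving out a library could hardly have turned their sign. Of the 19, 14 passed with DESeq2's size factors, 15 with upper-quartile factors and 14 with a CPM of at least 1 in 3 libraries. The number of higher genes was 31 with library totals only, 44 with no filter, 49 with the name form as a term, 126 with DESeq2 and 8 at an absolute log2 fold change of at least 1. The number of lower genes was 3 with no filter, 15 with the name form as a term and 61 with DESeq2. Limma-voom gave 14 and 0, and limma on the rlog values 17 (15 of the 19 among them) and 0. Leaving out 1 library gave 0 to 261 higher and 0 to 364 lower genes, the most without PT-I-PpoI replicate 3. Without that library all PT-I-PpoI libraries have names without a hyphen. Of the calls made without it 65 were also made between the name forms, but the contrasts share libraries, so this overlap tests no cause. With the replicate number as a block 33 genes were higher and 7 lower, all 19 included. Same-numbered libraries' deviations from their group means correlated at 0.219, -0.128 and 0.163, and PT-I-PpoI replicate 2 correlated best with wild type replicate 1. Every positive correlation across groups was between libraries of the same name form. These values therefore cannot tell whether the numbers pair the samples.

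With an estimated correlation the camera adjusted p was 0.583 for tubular injury, 0.595 for the convoluted proximal tubule, 0.479 for interferon-stimulated genes, 0.176 for the thick ascending limb and 0.0775 for the collecting duct. With the name form as a term as well, these were 0.283, 0.393, 0.393, 0.17 and 0.17. fry gave 0.285 for tubular injury, 0.316 for the convoluted proximal tubule and 0.224 for interferon-stimulated genes. Tubular injury ranged from 0.00299 to 0.0773 when 1 library was left out, the highest without wild type replicate 2. p53 targets, cell cycle and macrophage lists stayed uncalled under every alternative run on lists. At this depth and n, simulated 1.5-fold changes were recovered in 37.5% of cases, so smaller changes of single genes would mostly be missed. The simulated runs gave a mean of 152 calls, against 19 in the real counts, and with fewer calls the adjusted threshold is harder to pass. Larger changes may thus be missed in the real counts too.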

Other observations

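This part repeats some values of the planned comparisons of the groups by edgeR, DESeq2 and camera. All its other tests were chosen after the main results had been seen, except the counts of lists over other splits and the arms of the clock used for time of day. The libraries differed more by the form of their name than by group. With the group as a term, 248 genes were higher and 180 lower in the 3 hyphenated libraries than in the 3 others (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The 17 genes of the fixed clock list had a median 0.73 higher in the hyphenated libraries (camera adjusted p = 2.20e-05; adjusted p = 0.323 with an estimated correlation). Of these 8 were higher and 2 lower. The genes that follow were chosen after their values were seen. Ciart differed by 4.03 ± 0.21 on the log2 scale (SE), Dbp by 3.76 ± 0.33, Per3 by 1.79 ± 0.15 and Per2 by 1.68 ± 0.16, while Npas2, of the opposite phase, differed by -2.28 ± 0.20. Among targets of PPAR-alpha, Pdk4, an inhibitor of glucose oxidation, differed by -3.42 ± 0.30 and Cyp4a14, a fatty acid hydroxylase, by -2.38 ± 0.20. Of the 30 fatty acid oxidation genes 10 were lower (adjusted p = 0.583 for the list with an estimated correlation). Xist had 51 read pairs in PT-I-PpoI replicate 1 and 1 to 4 in the other libraries, and Y-linked genes were counted in all 6.

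A candidate explanation for this split is a different time of day at collection. If so, the light-phase and dark-phase arms of the clock should move apart, and this was tested on 8 clock genes whose own values had not been seen in this contrast. However, 7 of them belong to the clock list, whose upward result had been seen. The lower level of Npas2, of the opposite phase, already pointed to a fall of the dark-phase arm. The direction of both arms could thus be foreseen, so this test adds little to the clock genes named above. The light-phase arm (Nr1d1, Per1, Bhlhe41, Hlf) had a median log2 difference of 0.84 and the dark-phase arm (Arntl, Clock, Nfil3, Cry1) one of -1.47, with Clock itself at 0.02, a gap of 2.313. Sequencing depth was argued against, since totals overlapped between the forms, with means that differed by -2.56 M read pairs (hyphenated minus the others). The overlap rested on wild type replicate 3 (20.9 M), as the other hyphenated libraries had the lowest totals (13.6 and 14.3 M). Feeding state or a shared batch stays open and untested, and no label gives a time of collection.

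A second pattern is that the thick ascending limb and collecting duct lists were higher in PT-I-PpoI and the lists of the convoluted and straight proximal tubule lower, with adjusted p = 0.176, 0.0775, 0.595 and 0.585 with an estimated correlation and with 0 of 50 proximal tubule genes past edgeR's test, 2 lower with the name form as a term and 6 lower by DESeq2. For the thick ascending limb and collecting duct, the tables argue against the name form as the whole cause. With the form as a term, the score of all 29 genes of these lists differed by 0.439 (SE 0.032, against 0.455 without the term). That of the 50 proximal tubule genes differed by -0.15 (SE 0.046, against -0.233 with SE 0.124 without the term). However, scores of the convoluted and straight lists reached 0.11 and 0.05 in PT-I-PpoI and overlapped wild type, which began at -0.01 and -0.03. With 1 library of a group in each form, this cannot decide the question for proximal tubule genes. A lower share of proximal tubule cells alone would raise every other segment alike. The thick ascending limb score rose over the distal convoluted tubule score by 0.692 (SD 0.176, with 0.92 and 0.40 within libraries without and with a hyphen). Both lists were compared after their medians (0.44 and -0.18) had been seen, and the distal convoluted tubule medians differed in sign between the forms. Endothelial and podocyte genes also had medians above 0 (0.23 and 0.19), so this explanation stays open. More medulla in the dissected tissue may account for the pattern, but its score was written after the first results had been seen. A medulla score (Slc14a1, Slc14a2, Slc6a12, Wnt7b, S100a6) minus a cortex-only score was higher by 1.273 (SD 0.426). It lay at 0.403 or more in PT-I-PpoI and 0.013 or less in wild type. Without Slc14a2, which had been seen before the list was written, the difference was 0.97 (SD 0.40). The groups then lay at 0.22 or more and 0.075 or less. Leaving out Slc14a2 does not make the score independent of the first results, so it cannot decide the question. None of these medulla genes passed edgeR's test without the name form as a term (adjusted p = 0.105 for Slc14a2 to 0.436 for S100a6). Straight proximal tubule genes, which the outer medulla also holds, had a median of -0.33 all the same, and a response of distal segments to I-PpoI in the neighbouring proximal tubule stays open and untested.

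The 6 samples can be split in 10 ways into 3 and 3, too few for a share under 0.05. Of these, 2 gave at least 19 genes, the real one and the split by name form, which gave 363 and so points to a structure of the samples. With lists, 2 gave at least 13, the real one with 13 and the split by name form with 14. The other 8 splits called 0 genes each and 0 to 9 lists. With the name form as a term, 49 genes were higher and 15 lower, and 10 of the 13 lists were still called, or 0 with an estimated correlation as well (smallest adjusted p = 0.17).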
